A study of Mus musculus with 36 samples.

How the data were processed

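RNA of mouse mesenteric lymph nodes was measured on 2 kinds of Affymetrix oligonucleotide array that carry different probe sets, named here array A and array B. Per the labels, the nodes came from mice given phosphate-buffered saline (PBS, day 0) or the soluble lymphotoxin-beta receptor for 1, 2, 3, 27 or 35 days, with 3 samples per group on each array, 36 measurements in all. The soluble receptor is a decoy that binds the ligands of the receptor. The labels describe no saline group beyond day 0 and no group given a control fusion protein, so day of treatment, day of harvest and exposure to a foreign protein were not separated. Whether the 3 samples of a group came from separate mice is not given in the sources used here, so p-values measure the spread between these samples only. The source label of 1 day 1 sample on array B holds an unrelated phrase, and its group was taken from its title and description.

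The authors deposited 1 intensity per probe set and array on a linear scale, never negative, and the software, background correction and scaling behind it are not given in the sources used here. The deposited intensities were already on a common scale, since the array medians ran from 273 to 299.5 on array A and from 149.9 to 165.2 on array B, a ratio of 1.1 on each, and they were used without further scaling. The arrays carried 22626 and 22511 probe sets besides 64 control probe sets each, which stayed out of the tests. Of these probe sets, 20380 on array A and 14661 on array B were listed under 1 gene symbol, 691 and 245 under several, and 1555 and 7605 under none. Genes were named only from probe sets with 1 symbol in the platform annotation.

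Intensities below the 20th percentile of their table (122.6 on array A, 76.57 on array B) were raised to it and all were taken to log2. Probe sets above the table's median on at least 3 of the 18 arrays were tested, 12231 on array A and 12516 on array B. Each table was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with all 6 groups in 1 fit and no covariate. Each day was contrasted with day 0, the mean of days 27 and 35 (late) with the mean of days 1, 2 and 3 (early), and day 35 with day 27, and an F test asked whether any group differed. The early mean and the late mean were each contrasted with day 0 as well. P-values are two-sided, adjusted by the Benjamini-Hochberg method within table and contrast, and called at 0.05. All log2 changes are treated minus PBS, or late minus early, with the standard error (SE) of the fit. The number of arrays limits the precision.

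A set of 25 gene lists (stromal and endothelial cells, lymphocyte and myeloid classes, signalling, matrix, metabolism and possible neighbouring tissue) was written before the data were examined, as were the tests and the rule for naming genes. Lists were tested on array A with camera at a preset inter-gene correlation of 0.01, over 7801 genes with the brightest tested probe set standing for each gene, and again with an estimated correlation. Lists with fewer than 5 members on array A got no test, which left 24. Member counts take a gene from array A where tested and otherwise from array B. Genes named for a day against day 0 are the 6 largest rises and falls on array A and the 3 largest on array B among calls with 1 symbol and no overlap between the 3 samples of the day and the 3 PBS samples, and for late against early the 10 and 4 largest. The rule also takes up to 4 members with the smallest p of each called list and of the adipocyte, pancreas, intestine and erythroid lists. Another 20 genes tied to lymphotoxin signalling and lymph node stroma were fixed in advance, of which 6 had no tested probe set that names them alone and are not reported here. Genes outside this rule are marked as chosen after their values were seen.

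The procedure was tested on simulated arrays with the real means and spreads, in which 200 probe sets were changed at days 27 and 35. Of 67 probe sets changed by 0.5 (log2), the day 35 contrast called 92.5% among 12231 on array A and 79.1% among 12516 on array B. It called 100% of those changed by 1 or 2. Among 24 simulated lists over 7801 genes, camera called both of the 2 changed lists in the late contrast and 0 of 20 lists that shared no gene with them. The simulated genes varied independently, while the correlation estimated in the real lists reached 0.42 (adipocyte list). The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

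Alternatives covered the scaling (quantile, common median), the floor, the filter, the variance model, array weights, the replicate number as a block, fits of only the groups compared, a 2-fold threshold, the inter-gene correlation, the choice of probe set and the omission of single arrays. Added after seeing the data were a fit without the 3 samples that had the lowest array weights on array A (day 3 sample 3, day 27 sample 2 and day 35 sample 3) and a fit with the arrays' mean of the small respiratory chain subunits as a covariate. These subunits were picked because such genes had fallen late. On array A their mean was lower in every late sample than in any other except day 3 sample 3. The covariate thus overlaps with late treatment, and a call lost with it may reflect that overlap alone. The sources used here do not say that samples with the same replicate number share an animal or a day, and the numbers were not used as pairing. No array was a copy of another. The highest correlation within a group was 0.9923 on array A and 0.9754 on array B, and the lowest 0.9628 and 0.9146. Between groups the highest was 0.9912 and 0.9813. On array B at least 1 pair of samples from different days thus correlated better than any pair within a group.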

Results

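Gene expression was measured in mesenteric lymph nodes of mice given PBS or the soluble lymphotoxin-beta receptor, a decoy for the ligands that maintain lymph node stroma, for 1, 2, 3, 27 or 35 days. Each of the 6 groups had 3 samples on each of 2 arrays, and every probe set was compared with PBS in a limma fit of its own table. The question was which transcripts of the node follow treatment within days and which over weeks. Array medians ran from 273 to 299.5 intensity units on array A and from 149.9 to 165.2 on array B.

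**Figure D1:**
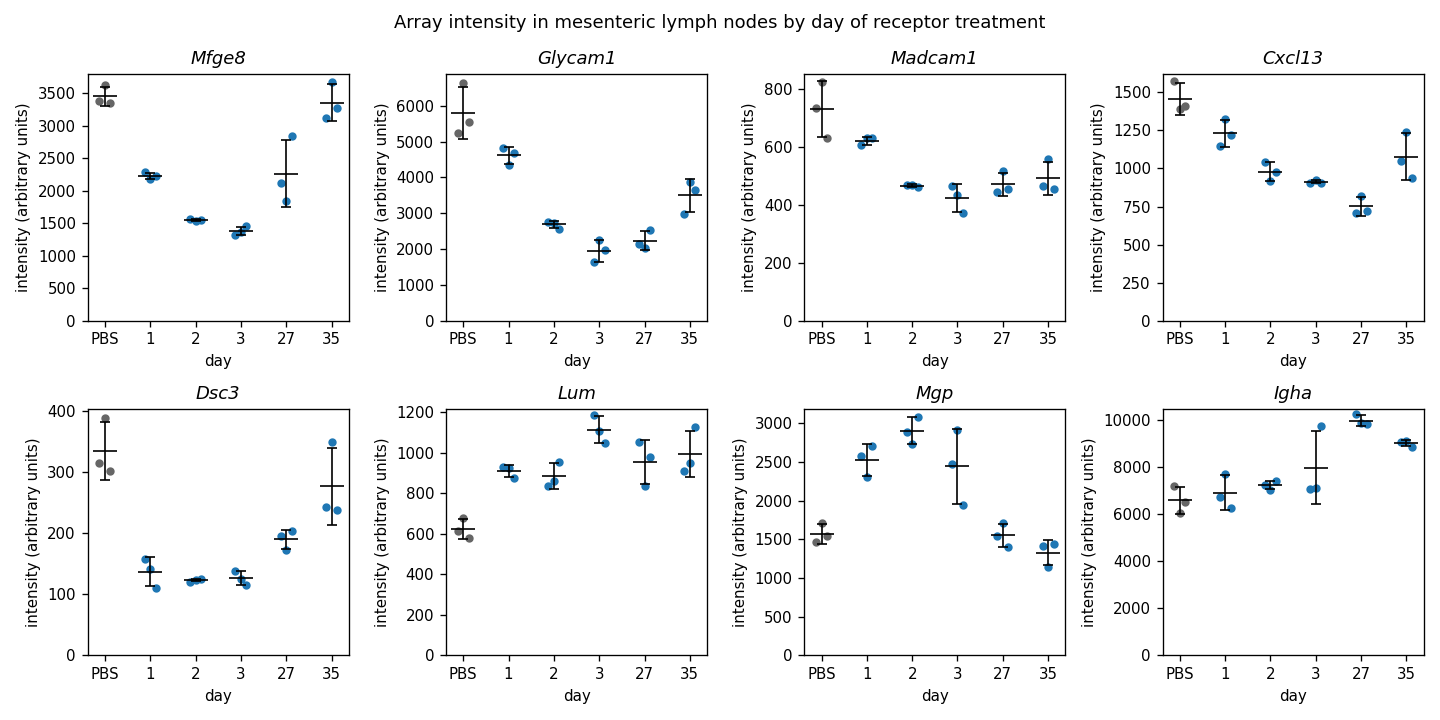
Intensity of 8 genes (vertical axes, linear, from 0) in PBS samples (grey) and after 1 to 35 days of receptor treatment (blue), on array A except Dsc3 on array B. Points are samples, and bars give the mean and SD of 3. Mfge8 averaged 3449 in PBS samples, 1380 at day 3 and 3354 at day 35, while Mgp averaged 1570, 2443 and 1330.

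After 1 day the desmosomal cadherin Dsc3 was the only uniquely named gene that fell. Its intensity on array B was 335 ± 47.3 (SD, n = 3) in PBS samples and 137.1 ± 24.2 (n = 3) at day 1, a log2 change of -1.30 (SE 0.15, adjusted p = 0.00057). Its probe set on array A changed by -0.64 (SE 0.096, adjusted p = 0.029). Mfge8, a secreted protein of follicular dendritic cells that tags dying cells for uptake, stood at 2228 ± 48.3 against 3449 ± 149 (n = 3 each). With a log2 change of -0.63 (SE 0.11, adjusted p = 0.0557) it did not pass the threshold. The vascular addressin Madcam1 (-0.22), the L-selectin ligand Glycam1 (-0.32) and the follicular chemokine Cxcl13 (-0.24) did not pass it either, each with an adjusted p of 0.998. In all, 2 probe sets on array A and 1 on array B were called, all lower. The other probe set on array A was listed under several symbols. On array A 411 probe sets had an unadjusted p under 0.05. The limma count on array A was 0 whichever of the 6 arrays was left out, which ended the call of Dsc3 there (adjusted p up to 0.25). On array B 4 were called without day 1 replicate 1.

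At day 2 some transcripts of follicular dendritic cells and of high endothelial venules, the vessels through which lymphocytes enter the node, had fallen, 3 of the 12 tested genes in each list. Madcam1 belongs to both lists and counts in each, here and at later days, so the 2 lists are not separate evidence. Mfge8 fell from 3449 ± 149 to 1548 ± 15.7 (log2 change -1.16, SE 0.11, adjusted p = 2.8e-05). Glycam1 fell from 5807 ± 727 to 2688 ± 107 (-1.10, SE 0.12, adjusted p = 0.00011; mean ± SD, n = 3 each). Cxcl13 (-0.73 and -0.57 on its 2 probe sets), Madcam1 (-0.64), the ubiquitin-like modifier Ubd (-0.63) and the cadherin Dsg2 (-0.74, with its 2 other probe sets at -0.12 and -0.31 and not called) fell as well. Among genes of the second array, Dsc3 (-1.44) and the secreted interleukin decoy receptor Il22ra2 (-0.95, from 394.3 ± 41.4 to 202.8 ± 3.57, n = 3 each) fell. The matrix genes Mgp, an inhibitor of calcification (0.89, SE 0.12, adjusted p = 0.0036), and Lum, a collagen-binding proteoglycan (0.50, SE 0.095, adjusted p = 0.046), rose with the growth factor binding protein Igfbp4 (0.56, adjusted p = 0.0498, with its 5 other probe sets at 0.21 to 0.37 and not called).

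Of 12 tested members of the follicular dendritic cell list 3 fell at day 2 and 9 did not pass, or 6 lower and 1 higher adjusted over the list alone. Of 12 members of the high endothelial venule list 3 fell and 9 did not pass, or 4 lower adjusted over the list alone. Across array A 14 probe sets were called, 11 lower and 3 higher, and across array B 3, all lower. With any 1 of the 6 arrays left out 4 to 7 were called on array A and 1 or 2 on array B. The calls of Lum (adjusted p up to 0.37) and Ubd (up to 0.21) ended whichever array was left out. Those of Madcam1 (up to 0.1) and Il22ra2 (up to 0.12) ended with any array except PBS replicate 3. The call of the Cxcl13 probe set at -0.57 ended with any array except day 2 replicate 1 (up to 0.12). That of its other probe set ended with PBS replicate 2 and day 2 replicate 3 (up to 0.067). With no filter on dim probe sets the calls of Lum, Ubd, Madcam1, Il22ra2 and 1 probe set of Cxcl13 ended. The call of Igfbp4, close to the threshold, was not recomputed with arrays left out or under other settings, so its stability is unknown.

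By day 3 Glycam1 had reached 1954 ± 303 (n = 3), a log2 change of -1.58 (SE 0.12, adjusted p = 6.93e-07), and Mfge8 1380 ± 66.6 (-1.32, SE 0.11, adjusted p = 1.59e-06). Cxcl13 (-0.89 and -0.67), Madcam1 (-0.78), Dsc3 (-1.40 on array B) and Il22ra2 (-1.03) were also lower. Among the genes that rose on array A were Lum (0.83, SE 0.095, adjusted p = 0.00013), the iron exporter Slc40a1 (0.66, and 0.25 on another probe set, not called), Mgp (0.62), the macrophage receptor Adgre1 (0.62) and the collagen Col14a1 (0.54, and 0.31 on another probe set, not called). The actin-bundling protein Fscn1 rose by 0.60 on 1 probe set, while its 3 other probe sets lay at -0.05 to -0.01.

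Also lower at day 3 were the glycosyltransferase Ogt (-0.96, with its 4 other probe sets between 0.03 and 0.20), the transcription factor Foxp1 (-0.74, 1 of its 6 other probe sets called as well) and, on array B, Pik3ip1 (-0.73, and -0.40 on another probe set, not called), an inhibitor of a lipid kinase. The only rise on array B was Gm38440 (0.69, adjusted p = 0.032). At day 3 the follicular dendritic cell and venule lists each had 3 of 12 members lower, or 4 each adjusted over the list alone. In the macrophage list 2 of 26 members rose (Adgre1 and Clec4n) and 1 fell (Lyz2, -0.36), or 5 and 2 adjusted over the list alone. Clec4n and Lyz2 were chosen here after their values were seen. In the matrix list 3 of 36 rose and 33 did not pass, or 8 higher adjusted over the list alone. Array A gave 68 calls, 51 lower, and array B 10, of which 9 were lower. Leaving out any 1 of the 6 arrays gave 16 to 31 calls on array A and 2 to 5 on array B. The calls of Slc40a1 (adjusted p up to 0.17) and Gm38440 (up to 0.32) ended whichever array was left out. Those of Adgre1 (up to 0.14) and Col14a1 (up to 0.15) ended with any array except PBS replicate 2. The call of Mgp (up to 0.12) ended with PBS replicates 1 and 3 and day 3 replicates 1 and 2, and that of Fscn1 (up to 0.25) with PBS replicates 1 and 3 and day 3 replicates 2 and 3. That of Pik3ip1 (up to 0.091) ended with PBS replicates 2 and 3 and day 3 replicate 2. No filter on dim probe sets ended these calls and that of Il22ra2, and the small-subunit covariate, chosen after seeing the data, ended those of Slc40a1, Adgre1, Col14a1 and Fscn1. Day 3 replicate 3 stood apart in its mean of small respiratory chain subunits, at -0.252 against 0.0916 and 0.182 in the other day 3 samples.

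Taking days 1 to 3 as a mean, the follicular dendritic cell list was lower than PBS (camera adjusted p = 3.2e-09) and so was the high endothelial venule list (4.8e-06). Both calls held with an estimated correlation (adjusted p = 0.02 and 0.027). The extracellular matrix and fibroblast list was higher (3.2e-09, but adjusted p = 0.21 with an estimated correlation), with 3 of 36 members called, Mgp (0.73), Lum (0.63) and the collagen Col3a1 (0.56), and 11 adjusted over the list alone. Adjusted over the list alone 5 of 12 follicular dendritic cell genes and 4 of 12 venule genes were lower, where 3 of each passed over all probe sets. Members of the follicular dendritic cell list that fell were Mfge8 (-1.04), Madcam1 (-0.55) and Cxcl13 (-0.50), while the retinol-esterifying enzyme Lrat stood at -0.31 (adjusted p = 0.265). Those of the venule list were Glycam1 (3087 ± 1210 in 9 early against 5807 ± 727 in 3 PBS samples), Ubd (-0.60) and Madcam1, while Gcnt1 stood at -0.61 (adjusted p = 0.359). Leaving out single arrays ended the call of Col3a1 with any array except PBS replicate 2 and day 2 replicates 1 and 2 (adjusted p up to 0.46). They ended the call of Ubd with PBS replicates 2 and 3 (up to 0.067), of Madcam1 with PBS replicate 2 (0.081) and of Cxcl13 with PBS replicate 1 (0.086).

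The macrophage and interferon response lists were also called higher early (camera adjusted p = 0.00046 and 0.0048) and the adipocyte list lower (0.0052), but with an estimated correlation these had adjusted p = 0.62, 0.69 and 0.69. Within the macrophage list the endotoxin co-receptor Cd14 rose (0.34, SE 0.062) and the lysozyme gene Lyz2 fell (-0.27, SE 0.051), while Clec4n (0.26) and Timd4 (-0.51) did not pass. The call of Lyz2 ended with any array left out except day 1 replicate 2 and day 3 replicate 3 (adjusted p up to 0.33). That of Cd14 ended without any 1 PBS replicate, day 1 replicate 1 or day 2 replicate 1 (up to 0.33). In this list 1 of 26 was higher and 1 lower, or 4 and 2 adjusted over the list alone. Of 28 interferon response genes 0 passed in limma, over all probe sets and adjusted over the list alone, and 4 had an unadjusted p under 0.05. Among these 28 were Ifit3 at 0.24, Ifi47 at 0.24, Gbp2 at 0.16 and Oas1a at 0.12. Of 17 fat cell genes 0 passed in the same ways and 3 had an unadjusted p under 0.05. Among these 17 were Pck1 at -0.42, Plin4 at -0.35, Pparg at 0.24 and Fabp4 at -0.14. In all 6 of 24 lists were called early. Over all 12231 probe sets of array A 5 were higher and 14 lower in this contrast.

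The receptor, its ligands and its transcription factors did not pass. Of 22 tested members of the lymphotoxin and NF-kB pathway list 0 passed in limma on each of the 5 days and in the late against early contrast, over all genes and adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 2, 4, 2 and 6 on the 5 days and 3 late against early. Without the 3 samples of low array weight, a choice made after seeing the data, 3 were higher at day 27, 3 at day 35, and 5 were higher and 1 lower late against early. At day 3 Ltbr, the receptor itself, stood at 0.02 (SE 0.13), its ligand subunits Ltb at 0.11 (SE 0.11) and Lta at -0.10 (SE 0.11), and the noncanonical transcription factors Nfkb2 at -0.22 (SE 0.098) and Relb at 0.06 (SE 0.095). The adhesion molecules Vcam1 (-0.02, SE 0.074) and Icam1 (0.04, SE 0.082), the venular chemokine receptor Ackr1 (0.01, SE 0.1) and the complement receptor Cr2 (-0.16, SE 0.092) did not pass at day 3 either. Clu, a chaperone abundant in follicular dendritic cells, had its brightest probe set at -0.30 (SE 0.075, adjusted p = 0.0983), while another of its probe sets fell by 0.42 (adjusted p = 0.036).

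At day 27 Glycam1, Cxcl13, Madcam1 and Mfge8 were lower than in PBS samples. Glycam1 read 2233 ± 261 (n = 3; log2 change -1.38, SE 0.12, adjusted p = 5.26e-06), Cxcl13 677.4 ± 52.5 against 1519 ± 55.6 in PBS samples (n = 3 each; -1.17, SE 0.11, adjusted p = 8.3e-06), Madcam1 -0.63 (SE 0.1) and Mfge8 -0.63 (SE 0.11, adjusted p = 0.0031). The other probe set of Cxcl13 read 751.1 ± 62 against 1457 ± 102 (n = 3 each; -0.96, SE 0.094, limma adjusted p = 1.4e-05). On array B Il22ra2 (-0.99), Timd4, a receptor for dying cells on resident macrophages (-0.92), and the oxidase subunit Cybb (-0.90, and -0.44 on another probe set, not called) fell. Slc40a1 (0.78), Adgre1 (0.65), Lum (0.61) and Nabp1 (0.58) rose, with the other probe sets of Slc40a1 (0.42) and Nabp1 (0.23) not called, as did Fscn1 (0.67, with its 3 other probe sets at -0.23 to -0.06). The immunoglobulin A heavy chain gene Igha rose by 0.60 (SE 0.11, adjusted p = 0.0038), with its 2 other probe sets at 0.59 and 0.60 and called as well. In a fit of only these 2 groups the calls of Mfge8 (adjusted p = 0.056), Adgre1 (0.07) and Fscn1 ended. With the mean of the small respiratory chain subunits as a covariate, chosen after seeing the data, those of Igha (0.069), Fscn1 (0.11) and Adgre1 ended.

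Other falls at day 27 were the beta globin gene Hbb-b2 (-1.32, SE 0.3), Ogt (-1.25, its 4 other probe sets at -0.04 to 0.21), Septin1 (-0.90) and the ribosomal protein homologue Rps27l (-0.87, with its 2 other probe sets at -0.56 and -0.76). Of the 12 follicular dendritic cell genes 3 fell and of the 12 venule genes 3 fell, while 5 of 36 matrix genes rose. Adjusted over the list alone these were 4 lower for follicular dendritic cells, 3 lower and 1 higher for venules, and 9 higher for the matrix. In the same samples 10 of 48 small respiratory chain subunits were lower, with a median of -0.29, and 0 of 33 large mitochondrial enzymes, with a median of 0.004. Array A gave 389 calls, 318 of them lower (81.7%), and array B 41, all lower. On array A 714 were called without day 27 replicate 2 and 137 to 227 without any other single array. On array B the count was 3, 0 and 4 without PBS replicates 1, 2 and 3 and 3 without day 27 replicate 3. The call of Hbb-b2 ended without PBS replicates 2 and 3 and day 27 replicates 1 and 3 (adjusted p up to 0.098), and that of Cybb without any 1 PBS replicate or day 27 replicate 3 (up to 0.1). That of Timd4 ended without PBS replicates 1 and 2 and day 27 replicate 3 (up to 0.095) and that of Il22ra2 without PBS replicate 2 (0.095). No filter on dim probe sets also ended the calls of Hbb-b2 and Cybb, and the covariate that of Hbb-b2.

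At day 35 the collagen gene Col1a2 showed the largest rise on array A among the genes named by rule. It rose by 0.90 (SE 0.13, adjusted p = 9e-04; 0.39 on its other probe set, also called), Col3a1 by 0.76 (SE 0.13) and Lum by 0.67 (SE 0.095). In the matrix list 10 of 36 genes passed, all higher, or 18 higher and 1 lower adjusted over the list alone. Glycam1 (-0.73, SE 0.12), Madcam1 (-0.57, SE 0.1) and Cxcl13 (-0.44, SE 0.094, adjusted p = 0.0077) were lower than in PBS samples. This Cxcl13 probe set had stood at -0.96 at day 27. The other, at -1.17 at day 27, stood at -0.52 and was called too. Mfge8 read 3354 ± 283 against 3449 ± 149 (n = 3 each; -0.04, SE 0.11, adjusted p = 0.85). On array B Cd300lg, a sialomucin of venular and capillary endothelium, fell from 410.7 ± 47.2 to 192.1 ± 14.3 (n = 3 each; -1.09, SE 0.11, adjusted p = 0.00019). Also lower were Pck1, an enzyme of glyceride synthesis in fat (-1.23, and -1.27 on array B), the acyl-CoA carrier Dbi (-1.08, and -0.78 and -0.93 on its other probe sets, both called) and the monoglyceride lipase Mgll (-1.02, and -0.78 and -0.19, of which 1 was called). Of 12 genes each, 2 of the follicular dendritic cell list and 3 of the venule list were lower, Madcam1 counting in both, and the numbers were the same adjusted over the list alone. Of 17 fat cell genes 3 were lower, or 7 adjusted over the list alone. Of 18 lipid and cholesterol genes 3 were higher and 0 lower at day 35, or 6 higher adjusted over the list alone.

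Fscn1 (0.76, its 3 other probe sets at -0.20 to -0.16), Ankrd10 (0.80, its other probe set at 0.12) and Slc44a2 (0.77, its 2 other probe sets at -0.07 and -0.13) rose at day 35, as did Rpain (0.64, its 2 other probe sets at 0.03 and -0.20), 5430434I15Rik (0.65) and Stpg1 (0.62) on array B. In these samples 38 of 48 small respiratory chain subunits were lower, with a median of -0.45, and 3 of 33 large mitochondrial enzymes, with a median of -0.11. Ogt (-1.36, its 4 other probe sets at 0.11 to 0.30), Hbb-b2 (-1.19), Rps27l (-1.07) and the splicing factor subunit Snrpf (-1.37, array B) fell. Array A gave 900 calls, 683 lower and 217 higher, and array B 449, of which 361 were lower. The array A count was 333 without day 35 replicate 2 and 481 and 395 without PBS replicates 2 and 3. Array B gave 125 to 239 without any 1 of the 6 arrays. The calls of Stpg1 (adjusted p up to 0.16) and 5430434I15Rik (up to 0.17) ended whichever array was left out. Those of Hbb-b2 (up to 0.12) and Ankrd10 (up to 0.13) ended without PBS replicates 2 and 3 and day 35 replicates 1 and 2, and that of Slc44a2 (up to 0.13) without any 1 PBS replicate or day 35 replicate 2. With the arrays' mean of small respiratory chain subunits as a covariate, chosen after seeing the data, 1 probe set was called on array A and 1698 on array B, and Slc44a2 turned to -0.19.

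Over days 27 and 35 together 3 lists were called on array A. The matrix list was higher (camera adjusted p = 1.4e-05), with 11 of 36 members up, or 15 adjusted over the list alone. These included Lum (0.64), tenascin gene Tnc (0.55), Col5a2 (0.46) and the laminin chain Lamc1 (0.29, its other probe set at -0.06). The lipid and cholesterol list was higher (0.0074), with 5 of 18 up, or 7 adjusted over the list alone. Among them were the sterol synthesis enzymes Sqle (0.55), Dhcr7 (0.33) and Cyp51 (0.32) and the lipogenic regulator Srebf1 (0.31). The venule list was lower (0.012), with Glycam1 (-1.06), Madcam1 (-0.60) and Ubd (-0.51) called and the sialyltransferase St3gal6 at 0.14 (adjusted p = 0.22). With an estimated correlation each of the 3 had adjusted p = 0.57. Adjusted over the list alone 3 venule genes were lower, and 3 of 12 follicular dendritic cell genes were lower both ways, with a camera adjusted p of 0.065. Without PBS replicate 2 camera called 5 lists. The call of Cyp51 ended without any array except day 27 replicate 2 and day 35 replicate 1 (adjusted p up to 0.14). Without PBS replicate 3 those of Sqle (0.069), Dhcr7 (0.055) and Srebf1 (0.19) ended. Of 48 small respiratory chain subunits 36 were lower in the same contrast, with a median of -0.36. With the small-subunit covariate 1 of 36 matrix genes, 0 of 18 lipid genes and 2 of 12 venule genes passed. The covariate overlaps with late treatment, so these losses cannot tell a technical cause from treatment time.

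In direct comparison of late with early treated nodes, 3 follicular dendritic cell genes were higher and 1 was lower. Mfge8 was higher late by 0.70 (SE 0.069, adjusted p = 5.7e-06), Lrat by 0.48 (SE 0.064, array B) and Clu by 0.18 (SE 0.049, adjusted p = 0.019). Cxcl13 was lower by 0.20 (SE 0.061, adjusted p = 0.029). Of 12 tested members 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone, and camera gave adjusted p = 0.4. With the small-subunit covariate 2 were higher and 0 lower, as the calls of Clu (adjusted p = 0.73) and Cxcl13 (0.32) ended. Left-out arrays ended the call of Cxcl13 with day 1 replicate 2, day 2 replicate 1, day 27 replicates 1 and 3 and day 35 replicates 1 and 3 (adjusted p up to 0.078) and of Clu with day 27 replicate 3 and day 35 replicate 2 (up to 0.063). Dsc3 was higher on both arrays (0.50 and 0.83) and Serpina10, a protease inhibitor, by 0.37. Mgp averaged 2625 ± 348 in the 9 early and 1440 ± 187 in the 6 late samples (log2 difference -0.86, SE 0.079, adjusted p = 4.6e-06). On array B the small secreted protein gene Wfdc17 showed the largest difference, from 1342 ± 230 (n = 9) to 670.1 ± 136 (n = 6; -1.01, SE 0.1, adjusted p = 6.9e-05).

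The proliferation list was lower late than early (camera adjusted p = 0.0038, but adjusted p = 0.95 with an estimated correlation), with 8 of 27 members lower, the same number adjusted over the list alone. Among them were the replication clamp Pcna (-0.32), the chromatin protein Hmgb2 (-0.38), Ube2c (-0.37) and Stmn1 (-0.22). The lipid and cholesterol list was higher (0.024, and adjusted p = 0.95 with an estimated correlation), with 6 of 18 up and 1 down, or 7 and 1 adjusted over the list alone. Those higher included Sqle (0.40), the cholesterol exporter Abca1 (0.33), Dhcr7 (0.29) and Idi1 (0.26). With the small-subunit covariate, chosen after seeing the data, 0 of 18 lipid genes passed (adjusted p = 0.81 for Sqle, 0.97 for Abca1, 0.19 for Dhcr7 and 0.8 for Idi1). By the same fit 5 of 27 proliferation genes were lower, and the calls of Hmgb2 (0.057) and Ube2c (0.53) ended. Other genes that fell were the cytokine Mif (-0.61), Cks2 (-0.61), Snrpg (-0.56), the kinase Pim1 (-0.54), Nop58 (-0.52), Polr1d (-0.52), Pole4 (-0.52), Sec62 (-0.50) and Hint1 (-0.48). The second probe sets of Polr1d (-0.16), Pole4 (0.00), Sec62 (0.05), Hmgb2 (-0.10) and Abca1 (0.08) were not called. Cutc (0.41), Cbll1 (0.36), Cables1 (0.29), the fatty acid activating enzyme Acsl4 (0.28) and Snx16 (0.28) were higher, with the second probe set of Cbll1 (0.03) not called. The covariate ended the calls of Snrpg (adjusted p = 0.13), Nop58 (0.079), Pole4 (0.058), Hint1 (0.055), Cutc (0.32), Cbll1 (0.11) and Cables1 (0.052). The call of Cutc ended without any 1 sample of days 1, 2, 3 or 27 (adjusted p up to 0.088). Its day 35 samples were far apart, at 470.5 ± 256 (SD, n = 3) against 305.4 ± 11.6 (n = 3) at day 27. With single arrays left out its change ran from 0.20 to 0.52, so its size is uncertain. The call of Idi1 ended without day 1 replicates 2 and 3, day 2 replicates 1 and 3, day 3 replicate 1, day 27 replicates 1 and 3 or day 35 replicate 2 (adjusted p up to 0.11). Camera called 0 lists without the 3 samples of low array weight, a choice made after seeing the data. In the matrix list 5 of 36 were higher and 2 lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.37).

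Small subunits of the respiratory chain and large mitochondrial enzymes, 2 lists chosen after seeing the data, parted in these samples. Of 48 small subunits 44 were lower late than early and 0 higher, with a median of -0.37, against 4 lower and 1 higher of 33 large enzymes, with a median of -0.06. At the same time the 3' to 5' signal ratio of the beta-actin control on array A was 1.11 ± 0.0283 (SD, n = 6) in late and 1.013 ± 0.0306 (n = 3) in PBS samples (exact permutation test, two-sided p = 0.0119). The same ratio of the Gapdh control was 1.035 ± 0.0348 (n = 6) against 1.004 ± 0.011 (n = 3; exact permutation test, two-sided p = 0.19). A control probe set for a B1 repeat read 2068 ± 253 (n = 6) against 2997 ± 129 (n = 3; exact permutation test, two-sided p = 0.0119), and 1942 in day 3 replicate 3. Late against early gave 1880 calls on array A, 1271 lower and 609 higher, and 208 on array B, 178 lower. With the small-subunit covariate 445 and 383 were called, and array B gave 138, 120 and 102 without day 2 replicate 2, day 27 replicate 3 and day 35 replicate 1.

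**Figure D2:**
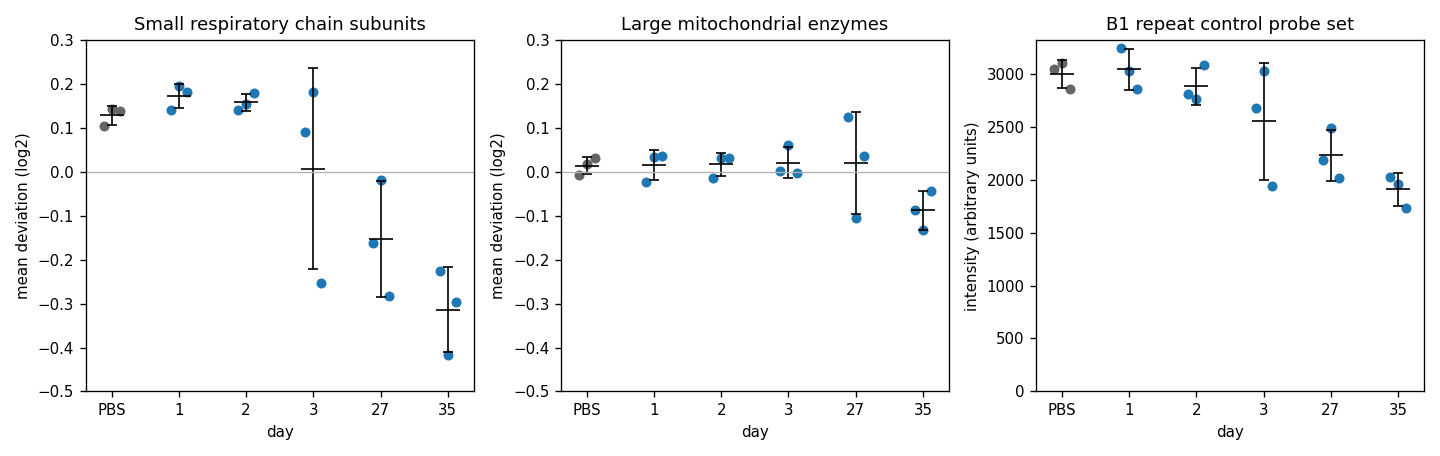
Each array A sample's mean deviation of small respiratory chain subunits and of large mitochondrial enzymes (log2, left and middle) and intensity of the B1 repeat control probe set (right, linear from 0), by day, PBS in grey. Points are samples, and bars give the mean and SD of 3. Small subunits lie at -0.418 to -0.0182 in the 6 late samples and at -0.252 in day 3 replicate 3, while the other samples lie between 0.0916 and 0.195.

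Between day 27 and day 35 no probe set passed the limma threshold on either array, with 815 on array A and 354 on array B at an unadjusted p under 0.05. Glycam1, Mfge8 and Cxcl13 had the smallest adjusted p among the genes fixed in advance. Glycam1 stood at 3496 ± 465 at day 35 against 2233 ± 261 at day 27 (n = 3 each; log2 difference 0.64, SE 0.12), Mfge8 at 3354 ± 283 against 2261 ± 514 (0.59, SE 0.11) and Cxcl13 at 1076 ± 154 against 751.1 ± 62 (0.51, SE 0.094), each with an adjusted p of 0.082. The Cxcl13 values are of the probe set at -0.96 at day 27, and its other probe set differed by 0.65 and was not called. Madcam1 differed by 0.06 (SE 0.1, adjusted p = 0.93) and Clu by 0.31 (SE 0.075, adjusted p = 0.37). Array A counts were 6 without day 27 replicate 3, 2 without day 35 replicate 3 and 1 without day 27 replicate 2.

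Across all 6 groups 943 probe sets differed on array A and 119 on array B by the F test, 9 and 11 of them with at least a 2-fold change on some day. Calls of neighbouring days overlapped. All 11 probe sets lower at day 2 were lower at day 3, 41 of 51 lower at day 3 were lower at day 27, and 278 of 318 lower at day 27 were lower at day 35, on array A. Independent lists of these sizes share 0.046, 1.3 and 18 probe sets. Of the rises on array A 2 of 3, 9 of 17 and 36 of 71 were shared in the same way (independent lists 0.0042, 0.099 and 1.3), and on array B 0 rises were shared. Part of the excess may come from the 3 PBS samples that every contrast shares, and the covariances of the log2 changes (0.0073, 0.014 and 0.023) stood beside values simulated for unchanged groups with shared controls of 0.0051, 0.0052 and 0.0051. Pairs of log2 changes correlated across probe sets, which are not independent replicates, at 0.52, 0.68 and 0.76 against 0.5 in the simulation. The array A count was 608 without day 35 replicate 2, and array B gave 76 without PBS replicate 2 and 59, 73 and 77 without day 35 replicates 1, 2 and 3.

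Markers of tissue around the node were followed in the same fits. Of 17 fat cell genes 2 fell late against PBS, Pck1 (-0.94, SE 0.2) and the lipid droplet protein gene Cidec (-0.49, SE 0.14), while Fabp4 (-0.22) and Scd1 (0.16) did not pass. Adjusted over the list alone 4 were lower and 1 higher, and camera gave adjusted p = 0.14. The call of Cidec ended without any 1 PBS replicate, day 27 replicate 3 or day 35 replicate 2 (adjusted p up to 0.11). The small-subunit covariate ended both calls (0.068 for Pck1 and 0.48 for Cidec). Late against early Pck1 (-0.52), Cidec (-0.40) and Pparg (-0.31) were lower and Scd1 (0.19) higher, with the second probe set of Scd1 (0.08) not called. With the covariate 0 of 17 passed (adjusted p = 0.12 for Pck1, 0.57 for Cidec, 0.82 for Pparg and 0.23 for Scd1). In all 4 were lower and 1 higher, or 5 and 3 adjusted over the list alone, with a median of 0.052 and a mean of -0.041 and camera adjusted p = 0.79. Of 8 exocrine pancreas genes and of 6 intestinal epithelium genes 0 passed in limma in the early, late or late against early contrasts, with 0 pancreas genes in each contrast and 1, 1 and 0 intestinal genes at an unadjusted p under 0.05. Camera gave the pancreas list adjusted p = 0.87, 0.5 and 0.47. The trypsinogen gene Prss2 stood at 0.20 (SE 0.12) and the trefoil peptide gene Tff3 at 0.25 (SE 0.11) late against PBS. Of 7 erythroid genes only Hbb-b2 passed, at -1.25 (SE 0.26) late against PBS and -0.71 late against early, while Slc4a1 stood at 0.24 (SE 0.11) and Car2 at 0.14 late against PBS. The covariate ended both calls of Hbb-b2 (adjusted p = 0.12 and 0.25). Camera gave the erythroid list adjusted p = 0.92, 0.91 and 0.91 in the early, late and late against early contrasts, with positive medians and negative means.

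The members named in this paragraph were chosen after their values were seen. Late in treatment 1 of 23 B cell genes was lower, 1 of 16 plasma cell genes was lower, and of 20 T cell genes 1 was higher and 2 were lower, or 1, 2, and 1 and 2 adjusted over the list alone. Over all 12231 probe sets of array A 704 were lower and 316 higher late against PBS, and the member counts were not tested against that share. Without the 3 samples of low array weight, a choice made after seeing the data, 3 B cell genes were higher and 1 lower, and with the small-subunit covariate 0 T cell genes passed. Of 6 germinal centre genes 0 passed in limma and 1 had an unadjusted p under 0.05 (1 higher adjusted over the list alone). Of 7 natural killer and cytotoxic cell genes 0 passed and 4 had such a p. Of 9 granulocyte and mast cell genes 0 passed and 0 had one. Of 16 dendritic cell genes 1 was higher and 1 lower, the same adjusted over the list alone. Of 26 macrophage genes 5 were higher, among them the growth factor receptor Csf1r (0.30) and the scavenger receptor Msr1 (0.22), and 2 lower, Lyz2 (-0.38) and Timd4, or 7 and 3 adjusted over the list alone. Without the 3 samples these were 8 and 2, and with the covariate 0 and 2. Late against early 0 macrophage genes were higher and 5 lower, or 0 and 7 adjusted over the list alone, the 5 being Cd68 (-0.33), C1qc (-0.24), Fcgr3 (-0.24), Apoe (-0.20) and Cd14 (-0.16). Without the 3 samples the balance turned, to 6 higher and 3 lower, and with the covariate it was 0 and 3.

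Camera called none of these classes other than the macrophage list early. Adjusted p in the early, late and late against early contrasts was 0.33, 0.7 and 0.94 for B cells, 0.11, 0.4 and 0.93 for germinal centres, 0.87, 0.94 and 0.79 for plasma cells, 0.28, 0.16 and 0.44 for T cells. It was 0.92, 0.29 and 0.37 for natural killer cells, 0.92, 0.84 and 0.78 for dendritic cells and 0.75, 0.96 and 0.79 for granulocytes. For macrophages late and late against early it was 0.7 and 0.26. Median, mean and test differed in sign late for B cells, plasma cells and dendritic cells, early for T cells, and late against early for germinal centres and B cells. Of 28 interferon response genes 1 was higher and 1 lower late, the same adjusted over the list alone, or 6 and 1 without the 3 samples of low array weight. Camera gave adjusted p = 0.7 late and 0.44 late against early. For proliferation camera gave 0.096 early and 0.15 late, with 2 of 27 genes lower late and a positive median (0.023) beside a negative mean (-0.037) and test.

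Among stromal and signalling lists, 1 of 10 reticular stromal genes rose early, the lymphocyte survival cytokine Il7 (0.33), and 1 fell, Cxcl13, or 3 and 1 adjusted over the list alone. Il7, and Reln below, were chosen after their values were seen. Of 6 homeostatic chemokine genes 2 were lower late, or 3 higher and 2 lower adjusted over the list alone. Of 18 blood endothelial genes 1 was lower late and of 13 lymphatic endothelial genes 1 was higher, Reln (0.26), or 2 and 1, and 3 higher, adjusted over the list alone. Of 13 complement genes 1 was lower late, and of 21 immediate early and heat shock genes 2 were higher and 1 lower, or 1, and 2 and 2 adjusted over the list alone. With the small-subunit covariate 0 genes of these last 4 lists passed late. Camera adjusted p in the early, late and late against early contrasts was 0.49, 0.96 and 0.44 for reticular cells, 0.94, 0.7 and 0.44 for chemokines, 0.94, 0.84 and 0.79 for the lymphotoxin pathway. It was 0.096, 0.94 and 0.44 for blood endothelium, 0.28, 0.2 and 0.44 for lymphatic endothelium, 0.92, 0.55 and 0.44 for complement and 0.19, 0.69 and 0.15 for immediate early genes. Median, mean and test differed in sign for reticular cells late, for chemokines early and late, for the lymphotoxin pathway and complement early, for immediate early genes late, and for blood endothelium and the venule list late against early. Late against early 0 of 12 venule genes passed in limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.93). Camera gave the lipid list 0.33 early.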

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

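The tests on the matrix rise, on the day 35 levels and of small subunits against large enzymes were chosen after the result was seen, as were the lists of small and large mitochondrial genes, and the splits of the samples were planned. Late and early treatment differed by limma's test of the difference itself in 1880 probe sets on array A and 208 on array B. Of the named genes, Dsc3 (0.495 on array A, 0.828 on array B), Cutc (0.412), Serpina10 (0.373), Cbll1 (0.362), Cables1 (0.286), Acsl4 (0.279), Snx16 (0.278), Snrnp48 (0.255), Pdlim5 (0.246), Rfx5 (0.244), Lrat (0.48), Nabp1 (0.474) and Nsun3 (0.323) were higher late (log2). Mgp (-0.864), Mif (-0.614), Cks2 (-0.606), Snrpg (-0.559), Pim1 (-0.538), Nop58 (-0.52), Polr1d (-0.519 and, on array B, -0.379), Pole4 (-0.518), Sec62 (-0.496), Hint1 (-0.484), Wfdc17 (-1.01), Bri3bp (-0.471) and Arsb (-0.383) were lower. Another probe set of Arsb stood at 0.08, and other probe sets of Cbll1 (0.03), Snrnp48 (0.11), Pdlim5 (0.01), Nsun3 (0.04), Nabp1 (0.13 and 0.31), Polr1d, Pole4, Sec62 and Bri3bp (-0.04) were not called either. The same test separated Mfge8 (0.698), Clu (0.177) and Cxcl13 (-0.204), the proliferation genes Hmgb2 (-0.377), Ube2c (-0.368), Pcna (-0.322) and Stmn1 (-0.224), and the lipid genes Sqle (0.397), Abca1 (0.328), Dhcr7 (0.294), Idi1 (0.262) and Scd1 (0.189). It also separated the fat cell genes Pparg (-0.305), Cidec (-0.4) and Pck1 (-0.518) and the globin gene Hbb-b2 (-0.706). Scd1, named above, belongs to the fat cell list, where 4 members were lower and 1 higher. Leaving out single arrays ended the call of Nsun3 with 11 of 15 (adjusted p up to 0.16), of Pck1 with 5 (up to 0.094) and of Hbb-b2 with day 27 replicate 1 and day 35 replicate 2 (up to 0.064). The mean of the small respiratory chain subunits as a covariate, chosen after seeing the data, ended the calls of Pparg (adjusted p = 0.82), Cidec (0.57), Pck1 (0.12), Hbb-b2 (0.25), Clu (0.73) and Cxcl13 (0.32). It also ended those of the 5 lipid genes, Hmgb2, Ube2c, Snrpg, Nop58, Pole4, Hint1, Cutc, Cbll1, Cables1, Pdlim5, Snrnp48 and Nsun3. In control probe sets outside the comparisons the late to PBS ratio of the beta-actin 3' to 5' signal was 1.1 on array A and 1.13 on array B (exact permutation p = 0.0119 each), and that of the Gapdh control was 1.03 and 1 (p = 0.19 and 0.94).

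The late falls of small respiratory chain subunits may come from a loss of short messages in the late arrays. Small subunits lay below large enzymes of the same organelle by a median difference of -0.306 (bootstrap interval -0.39 to -0.24), but falls of such subunits had led to the lists, so the difference describes the pattern and does not test this explanation, which stays open. A fall of mitochondrial energy metabolism as a pathway stays open, since the median of the large enzymes, -0.064 (interval -0.1 to -0.019), lies between the values that would speak for and against it. RNA degradation stays open too, since the actin ratio and the mean of the probe sets lower late correlated at Pearson's r = -0.0207 over 18 arrays after removing group means (one-sided permutation p = 0.48, two-sided 0.96; Spearman's rho -0.13, permutation p = 0.66; r = 0.03 without the 2 farthest arrays). Treatment time itself stays open as an untested biological difference.

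The early rise of extracellular matrix genes could come from more fat attached to the treated nodes or from a lower share of lymphocytes. The list's call rests on the preset correlation (adjusted p = 0.21 with an estimated correlation), and 3 of its 36 members passed. The adipocyte list, whose early values had already been seen, lay below the matrix list by a median difference of -0.176 (bootstrap interval over genes -0.29 to -0.11). This difference restates known values and was not an independent test of attached fat. No rise of fat cell genes was seen, with a list median of -0.056 and 0 of 17 members called. The follicular dendritic cell and venule lists, already seen to fall, together lay below the matrix list by -0.205 (interval -0.35 to -0.051). A lower share of lymphocytes raising every stromal marker alike would not give these falls. The difference restates them, however, and was not an independent test. The early medians of the reticular (0.095), blood endothelial (0.082) and lymphatic endothelial (0.089) lists beside that of the matrix (0.12) leave open a lower share together with a separate fall of follicle and venule transcripts, and a change in matrix-producing cells or a technical cause not weighed here stays open, untested.

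The probe sets that fell early may have returned towards PBS levels between day 27 and day 35. The 14 probe sets lower in the early contrast on array A changed by a median of 0.332 from day 27 to day 35 (bootstrap interval 0.13 to 0.48), a comparison that uses no PBS or early array. Of these probe sets 92.9% were higher at day 35 than at day 27, though Ubd was lower (-0.09) and Madcam1 changed little (0.06). The probe sets are not independent replicates, and Cxcl13 is among them more than once. The share therefore does not settle whether they were picked as low by chance, and limma called no probe set in this comparison. The labels describe no PBS group at either day, so age and any difference in handling stay open beside treatment time.

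Other splits of the same samples were counted for each comparison. For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05. On array A 1 of 10 splits, the real one, gave as many at day 1 (4, highest other 0), day 2 (17, 0), day 3 (29, 0), day 27 (113, 0) and day 35 (691, 0), and 10 of 10 gave 0 for day 35 against day 27. On array B it was 1 of 10 at day 1 (1, highest other 0), day 2 (3, 1), day 3 (7, 0), day 27 (16, 0) and day 35 (1191, 0), and 10 of 10 gave 0 for day 35 against day 27. For late against early 1 of 100 splits, the real one, gave as many on array A (1658, highest other 34). This argues against a chance split of single samples. Late and early are whole days of harvest, however, so chance differences between days or batches were not tested. On array B 3 of 100 splits gave as many (156, highest other 3520), but the splits take no account of same-numbered samples deviating together, so chance is not taken as excluded there. That array B split put day 1 and day 2 replicate 3, day 3 and day 27 replicates 2 and 3 and the day 35 samples on one side, and its count, many times the real one, points to a structure of the samples. With the replicate number as a block late against early gave 483 on array B. For the test across 6 groups 2 of 100 assignments gave as many on array A (943, highest other 1327). On array B it was 5 of 100 (119, highest other 1317, again several times the real count). On each array some shuffled assignment gave more than the real one, so chance is not taken as excluded on either. For the number of gene lists called by camera chance was not excluded early (20 of 100 splits, 6 lists, highest other 9), late (49 of 84, 3 and 10) or late against early (73 of 100, 2 and 11).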

How the results depend on the processing

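The fits without 3 samples of low array weight and with the small-subunit covariate were chosen after the data were seen, and the other settings were planned. Counts are for days 1, 2, 3, 27 and 35 against PBS, late against early, day 35 against day 27 and the 6-group test unless named. Of 137 called gene results, 2680 of 3000 recomputed values kept their call, 319 lost it and 1 reversed, Slc44a2 at day 35 (-0.19 with the covariate). The floor at another percentile ended no gene call, no filter ended 30 and the covariate 57. Losses with the covariate may reflect its overlap with late treatment alone. Except where the setting itself uses fewer samples or a larger minimum change, the cause was not tested. Signal near the floor limits dim probe sets.

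Quantile normalization gave 5 at day 1 and 4 for day 35 against day 27 on array A and 21 at day 27 on array B. A common median gave 619 at day 27 and 4 for day 35 against day 27 on array A and 19 at day 27 on array B. A stricter filter gave 4 at day 1 and 5 for day 35 against day 27 on array A, and 0 lists late against early. No filter gave 5, 3 and 17 at days 1, 3 and 27 and 7 for day 35 against day 27 on array B, and 4 lists late against early. Array weights gave 77, 536, 377, 2485, 3046, 4114, 464 and 4721 on array A and 152, 2298, 45, 345, 1432, 505 and, across 6 groups, 3031 on array B, where 1 sample (day 2 replicate 2) got a weight of 17.3, far above the others, and whether the weights converged was not checked. Fits of only the groups compared gave 4, 29 and 113 at days 1, 3 and 27 on array A and 16 and 1191 at days 27 and 35 on array B. A change of at least 2-fold left 0, 2, 2, 4, 6, 0 and, across groups, 9 on array A and 1, 3, 1 and 8 at days 2 to 35, 1 late against early and 11 across groups on array B. An estimated inter-gene correlation left 2 lists early, 0 late and 0 late against early. Without 3 samples of low array weight the counts were 9, 31, 1432 and 1831 at days 1, 2, 27 and 35, 3211 late against early, 6 for day 35 against day 27 and 2052 across groups on array A, 177, 134 and 77 at day 35, late against early and across groups on array B, and 0 lists late against early. The covariate gave 4 and 1 at days 1 and 35, 445 late against early and 57 across groups on array A, 19, 137 and 1698 at days 3, 27 and 35, 383 late against early and 52 across groups on array B, and 7 lists late and 6 late against early.

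With the replicate number as a block the count for day 35 against day 27 on array A was 1, and array B gave 2, 10, 68, 220 and 1327 on the 5 days, 483 late against early and 347 across groups. The block moved no other count by over 1.5 times. Among gene calls, those of Col3a1 and Lyz2 early, Lum at day 2, and Slc40a1 and Fscn1 at day 3 ended with it. Same-numbered samples deviated together above r = 0.1 in 18 of 45 pairs on array A and 34 of 45 on array B, and 9 and 16 of 18 samples correlated best with their own number, a hint from the data and not the design. Leaving out 1 sample at a time gave, on array A, 0 to 0, 4 to 7, 16 to 31, 137 to 714, 333 to 763, 1292 to 2419, 0 to 6 and 608 to 1368. On array B it gave 1 to 4, 1 to 2, 2 to 5, 0 to 33, 125 to 239, 102 to 276, 0 to 0 and 59 to 164, and 5 to 7 lists early and 3 to 5 late.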

Other observations

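These genes were chosen after their values were seen. At day 35 Nr1d1, a repressor in the circadian clock, was lower at -0.67 (SE 0.1, adjusted p = 0.0011; 387.8 ± 34.2 against 614.9 ± 13 in PBS samples, SD, n = 3 each, limma), as were the transcription factor Dbp at -0.52 and -0.72 on its 2 probe sets (adjusted p = 0.0091 and 0.0043) and Per1 at -0.37 (adjusted p = 0.036). The clock genes Clock (0.15), Arntl (0.20), Per3 (-0.05 and 0.13) and Nr1d2 (-0.02 and 0.09) were not called on array A at day 35, and no list of clock genes was tested. At day 27 Nr1d1 stood at -0.26 (limma adjusted p = 0.18) and the Dbp probe set at -0.52 above stood at -0.09 (0.7), neither called. Day of harvest was not separated from treatment, so these falls cannot be assigned to either. The immunoglobulin A gene Igha rose late on each of its 3 probe sets, by 0.555, 0.555 and 0.529 (adjusted p = 0.00049, 0.0011 and 0.00088), while Jchain, which joins its multimers, stood at 0.13 (adjusted p = 0.47). The 3 probe sets of Igha read the same gene and are not independent. On the probe set at 0.529 day 3 replicate 3, which was low in small respiratory chain subunits, read 9734. The other day 3 samples read 7075 and 7079, and the late samples 8842 to 10230. As given above, the small-subunit covariate ended the day 27 call of Igha. The light chain gene Igk was lower late on 1 probe set (-0.36, adjusted p = 0.015) and stood at -0.05 (adjusted p = 0.93) on another.

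On array B the endothelial gene Cd300lg fell late by 0.91 (SE 0.099, adjusted p = 0.00032) and was lower late than early (-0.58, adjusted p = 0.00047). The transporter gene Slco2b1 fell early by 0.51 and late by 0.41 (adjusted p = 0.024 and 0.017) on 1 probe set, while its 2 others stood at -0.27 and 0.19 early and were not called. The prion protein gene Prnp fell early on 1 probe set (-0.29, adjusted p = 0.049) but stood at -0.11 (adjusted p = 0.9) on another.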
